A study of Mus musculus with 9 samples.

How the data were processed

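RNA was measured in eosinophils, granulocytes of allergic and tissue inflammation, sorted from infiltrates of mouse quadriceps muscle. Per the labels' protocols, live cells positive for CD45 and Siglec-F and negative for CD11c, Gr1 and MHC class II were collected by flow cytometry, and libraries were made from their total RNA with a low-input kit. The 9 libraries fall into 3 groups of 3 by their titles: IL5Tg, mice that carry an interleukin-5 transgene; mdx, a dystrophin-deficient mouse strain that models Duchenne muscular dystrophy; and mdx_IL5Tg, which combines both. The design text calls the replicates biological. The strain label reads mdx for all 9 samples, IL5Tg included, which conflicts with the titles; groups were taken from the titles.

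The deposited table holds expected counts per gene, estimated by the authors with RSEM and not normalised, for 54146 genes. The submitters' processing notes name cutadapt 2.10, STAR 2.5.3, RSEM 1.3.0 and limma, with the mouse build mm10; their settings, the annotation and the strand setting are not given in the sources used here. RSEM shares reads that fit several genes among them by estimation, so values of near-identical paralogs (histone, Ear and class II genes among those named) and of overlapping genes (Cmtm1 and Cmtm2a) are uncertain. In all, 6.03% of values were not whole and were rounded to whole numbers. Column names give the group and an S number that the labels do not, so a column could be tied to its group but not to a numbered replicate; libraries are named here by group and S number. Positions come from GENCODE release M21 (GRCm38), in which 54079 gene identifiers were found without their version suffix. Of the genes in the table, 118 carry a symbol used more than once.

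Total counts ranged from 26752780 to 58368283 per library. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 15886, and libraries were scaled with TMM factors. Differences were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with all 9 libraries in 1 fit and a mean per group, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are log2, the error is the standard error recovered from the F statistic, and levels are TMM-normalised CPM (edgeR) as mean ± SD over 3 libraries. Gene lists fixed from textbook knowledge (28 in all) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 84 tests; members past the threshold are also counted adjusted over the list alone. No camera call held at the 0.05 threshold when the correlation was estimated from the data. Correlations between libraries lay between 0.957 and 0.987 within groups (Pearson's r across genes, log2 CPM), and no pair of libraries agreed within sampling noise.

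The groups, tests, lists and the rule for named genes were fixed before the data were examined, with 1 later change to the rule given below. The rule took, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold, at or above the median expression, with all 3 libraries of 1 group above all 3 of the other; predicted and pseudogene models, AC, AL and BC clone names and small or ribosomal RNAs were left out. After the data were seen, this exclusion was widened to names opening with RP23, RP24, CT, CR, CAAA or n-R, a departure from the fixed rule. It took out RP23-78F6.3, RP23-412L18.3 and RP23-241N10.4 in mdx_IL5Tg against IL5Tg (log2 -2.66, -2.62 and -2.44), and Hist1h2ak, Kif11 and Hist1h2ab took their places. It also took out RP23-359B23.11, at 6.00 in mdx against mdx_IL5Tg and 6.00 in mdx against IL5Tg, where Col11a1 and Spp1 came in. The rule also added every tested Trem family member and up to 4 members of each list with the smallest p. Other names are marked as chosen after their values were seen. The alternatives were DESeq2 1.42.0, limma voom with and without quality weights, RLE factors, library totals only, no filter, a stricter filter (50 counts in 3 libraries), removal of mitochondrial, haemoglobin and small RNA genes (the last by their biotype in release M21), only the groups compared, each library left out, and for lists an estimated correlation and fry, which tests a list against no change where camera tests it against the other genes. Chosen after seeing the data were the removal of IL5Tg S7 and mdx S5 together, per-library offsets for a trend with GC content, and the type 2 and repair list without Il5, its member that is the transgene. With 200 changed genes simulated, 66%, 78% and 70% of 4-fold changes were recovered in mdx_IL5Tg to IL5Tg, mdx to mdx_IL5Tg and mdx to IL5Tg. False calls were 1, 2 and 3 among 15570, 15612 and 15613 genes. At 3-fold the fit recovered 62%, 52% and 50%, at 2-fold 24%, 30% and 32% and at 1.5-fold 3, 0 and 3 of 50. More genes were called in the data, so these values may not carry over.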

Results

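Eosinophils sorted from mouse quadriceps muscle were profiled in 3 groups of 3 libraries: IL5Tg, mdx_IL5Tg and mdx. Total counts per library were 28965590, 30824793 and 26752780 in IL5Tg (S7, S8 and S9), 58368283, 43297851 and 44217823 in mdx_IL5Tg (S1, S2 and S3), and 41627444, 29200231 and 36464390 in mdx (S4, S5 and S6). The series title concerns Trem2, a lipid-sensing receptor of myeloid cells, in tissue eosinophils. The first principal component of log2 CPM held 42.3% of the variance and the second 22.6%.

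**Figure D1:**
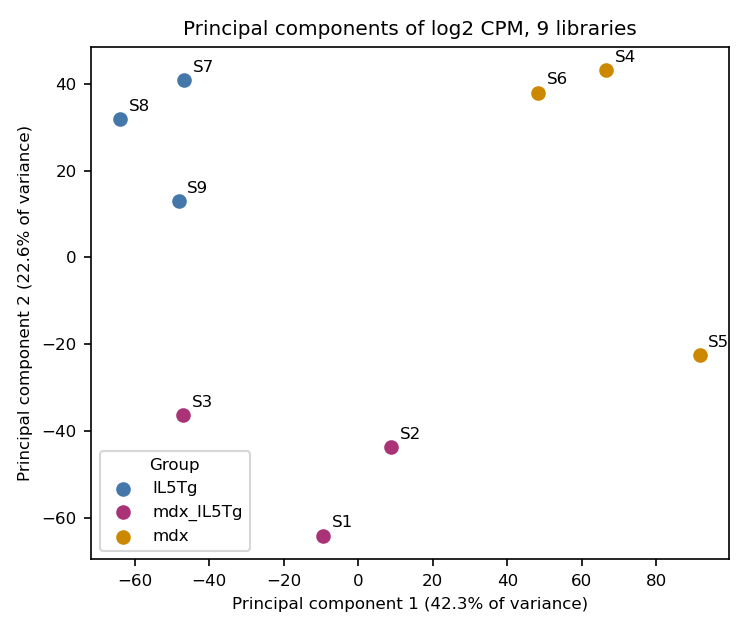
First 2 principal components of log2 CPM for the 9 libraries, with group by colour and library number beside each point. The 3 mdx libraries had the highest values on component 1, and mdx S5 lay apart from mdx S4 and S6 on component 2.

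The transgene label was checked by Il5, which ranged from 317 to 724 CPM in the 6 transgenic libraries and from 0.265 to 0.402 CPM in the 3 mdx libraries. Its means were 434 ± 105 CPM in IL5Tg, 695 ± 30.3 in mdx_IL5Tg and 0.334 ± 0.0682 in mdx (SD, n = 3). Dmd, the gene mutated in mdx, was at 5.79 ± 0.727, 2.20 ± 0.551 and 5.001 ± 2.11 CPM in the same order, and was chosen for this check after its values were seen. The mdx mutation is a nonsense change that leaves a transcript, so these levels do not check that label. Ccr3, the eotaxin receptor of eosinophils, chosen in the same way, was at 968 ± 124, 1372 ± 65.6 and 1017 ± 181 CPM. Mitochondrially encoded transcripts held 0.383% of counts in mdx S5, against 1.55% and 1.28% in mdx S4 and S6.

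Trem2 (ENSMUSG00000023992.14, protein coding, GRCm38 chromosome 17, 48346401 to 48354147) was lowest in IL5Tg at 0.186 ± 0.127 CPM, higher in mdx_IL5Tg at 2.12 ± 1.19 CPM and highest in mdx at 11.1 ± 4.96 CPM (SD, n = 3). It rose by a log2 change of 3.46 (SE 0.63, edgeR adjusted p = 0.016) in mdx_IL5Tg against IL5Tg. It rose by 2.39 (SE 0.50, edgeR adjusted p = 0.0084) in mdx against mdx_IL5Tg and by 5.85 (SE 0.65, edgeR adjusted p = 2.2e-04) in mdx against IL5Tg. Counts of Trem2 were 5, 10 and 2 in IL5Tg S7, S8 and S9. C1qb, a complement gene of macrophages, was at 1.02 ± 0.560, 9.69 ± 6.69 and 45.2 ± 17.0 CPM. The first of these calls ended without IL5Tg S7 (log2 3.40, edgeR adjusted p = 0.067), IL5Tg S9 (3.17, adjusted p = 0.052) or mdx_IL5Tg S1 (3.52, adjusted p = 0.061), and with limma voom (3.40, adjusted p = 0.082). Without IL5Tg S8 the change was 4.17 against IL5Tg in mdx_IL5Tg and 6.45 in mdx.

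Trem1, which amplifies inflammatory signals, rose by 1.55 (SE 0.17) in mdx_IL5Tg against IL5Tg, from 122 ± 11.1 to 355 ± 11.3 CPM. In mdx it was at 80.4 ± 19.1 CPM and fell by 2.14 (SE 0.18) against mdx_IL5Tg. Tyrobp, the adaptor that Trem2 signals through, fell by 0.79 (SE 0.14) in mdx against mdx_IL5Tg, from 412 ± 48.3 to 239 ± 33.2 CPM. Hcst and Treml2 fell there by 0.88 and 0.61. Treml4 was at 0.58 in the first and 0.23 in the second comparison. Trem3 had log2 changes of 0.79, -0.44 and 0.36 in the 3 comparisons and passed in none of them with edgeR. Of 7 tested members of the family and its adaptors, 2 rose in mdx_IL5Tg against IL5Tg (7 adjusted over the list alone, camera adjusted p = 5.9e-07, and adjusted p = 0.12 with an estimated correlation). In mdx against mdx_IL5Tg 4 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.0088, and adjusted p = 0.17 with an estimated correlation). Trem family genes called lower numbered 2 with library totals only. The call of Hcst ended without mdx_IL5Tg S1, mdx S4 or mdx S6 (edgeR adjusted p = 0.086, 0.089 and 0.079). The calls of Hcst and Treml2 ended with library totals only (edgeR adjusted p = 0.082 and 0.11). In mdx against IL5Tg, Trem2 and Treml4 rose and Trem1 fell, with Treml4 at 0.81 and Trem1 at -0.60 (2 and 1 adjusted over the list alone, camera adjusted p = 0.50); with GC offsets 1 rose and 2 fell. The median of that list was -0.089 and its mean 0.84, while camera's direction was up. The call of Treml4 ended without IL5Tg S7, mdx S4 or mdx S6, or with GC offsets (edgeR adjusted p from 0.054 to 0.099). The calls of Trem1 and Treml4 ended without IL5Tg S9 (edgeR adjusted p = 0.070 and 0.11). The call of Trem1 ended with library totals only (edgeR adjusted p = 0.096).

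**Figure D2:**
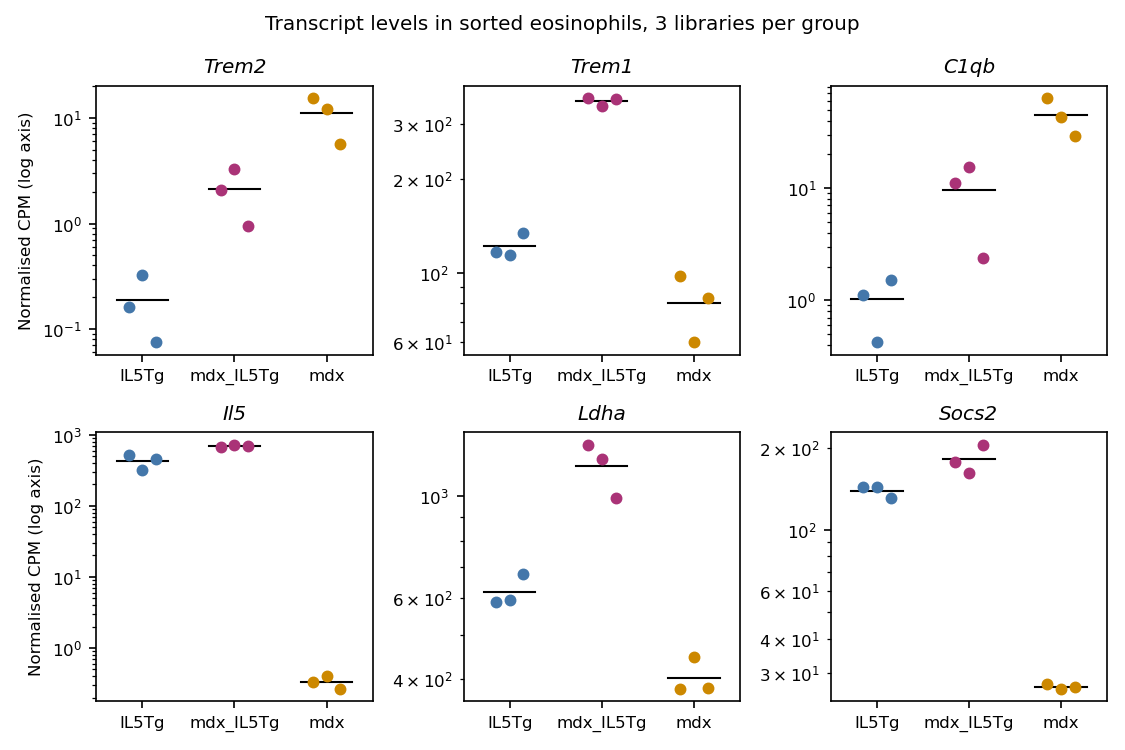
Normalised CPM on log axes for 6 genes in the 3 groups, with 1 point per library and a line at the group mean. Trem2 and C1qb had their lowest mean in IL5Tg and their highest in mdx, whereas Trem1, Ldha and Socs2 had their highest mean in mdx_IL5Tg and Il5 was near 0 in mdx.

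The comparison of mdx_IL5Tg with IL5Tg asked how cells sorted as eosinophils from transgenic mice differed with and without the dystrophic background. Most tested genes of glycolysis and the hypoxia response rose (13 of 18), as did 8 of 20 inflammatory genes, and 7 of 21 proliferation genes fell. Without mdx_IL5Tg S1 these counts were 7, 3 and 0, and with library totals only inflammatory calls numbered 5. Pfkl, a subunit of the glycolytic enzyme phosphofructokinase, rose from 66.3 ± 7.98 to 208 ± 33.8 CPM and Vegfa, the angiogenic growth factor, from 413 ± 54.3 to 997 ± 54.6 CPM (SD, n = 3). The largest rise under the naming rule was that of Col22a1 (chromosome 15, 71795795 to 72034227), a collagen of tissue junctions, from 1.43 ± 0.158 to 167 ± 8.61 CPM, a log2 change of 6.87 (SE 0.32, edgeR adjusted p = 4.0e-06). In all, 1147 of 15886 genes changed in edgeR, 691 higher and 456 lower; of those past 2-fold 200 were higher and 372 lower. In 35.9% of genes the groups did not overlap, against 10% by chance. Genes called higher and lower numbered 200 and 56 without IL5Tg S7, 295 and 174 without IL5Tg S8, 269 and 88 without IL5Tg S9, 108 and 2 without mdx_IL5Tg S1 and 213 and 41 without mdx_IL5Tg S2. They numbered 916 and 925 without mdx_IL5Tg S3, 690 and 262 without mdx S4, 1557 and 1084 without mdx S5 and 563 and 212 without mdx S6. The total was 1739 without IL5Tg S7 and mdx S5 together, which was run after seeing the data. Of the changed genes 60.2% were higher, and this split moved with the scaling and the libraries used. The share was 78.1% without IL5Tg S7, 75.4% without IL5Tg S9, 98.2% without mdx_IL5Tg S1, 83.9% without mdx_IL5Tg S2, 72.5% without mdx S4 and 72.6% without mdx S6. Most changed genes were lower in other alternatives, the higher share in mdx_IL5Tg against IL5Tg being 49.0% with DESeq2, 48.7% with voom quality weights, 24.1% with library totals only and 49.8% without mdx_IL5Tg S3. With library totals only the median log2 change of all genes went from -0.050 to -0.27.

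Of the 18 glycolysis and hypoxia genes tested 13 rose and 5 did not pass (17 adjusted over the list alone, camera adjusted p = 2.7e-22, and adjusted p = 0.17 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 1.82 (SE 0.17), Egln3, an oxygen-sensing hydroxylase, by 1.68 (SE 0.20), and Bnip3, a mitophagy receptor, by 1.58 (SE 0.19). Among NF-kB and cytokine genes 8 of 20 rose (13 adjusted over the list alone, camera adjusted p = 7.3e-10, and adjusted p = 0.14 with an estimated correlation). They included Cxcl3, a neutrophil-attracting chemokine, at 2.07 (SE 0.28), Il1rn, the interleukin-1 receptor antagonist, at 1.86 (SE 0.19), and Relb at 1.07 (SE 0.14). Of type 2 and repair mediators, a list that holds Il5, the transgene, 6 of 15 rose (6 adjusted over the list alone, camera adjusted p = 2.0e-07, and adjusted p = 0.14 with an estimated correlation), Il5 among them. Without Il5, an alternative chosen after seeing the data, 5 of 14 rose (5 adjusted over the list alone, camera adjusted p = 6.2e-07, and adjusted p = 0.14 with an estimated correlation), with Tgm2, a transglutaminase, going from 3129.8 ± 499 to 11429 ± 522 CPM and Thbs1 changing by 1.16 (SE 0.19). Il1r2, the decoy interleukin-1 receptor, rose by 2.02 (SE 0.17) and Cd101, an inhibitory surface receptor, by 2.89 (SE 0.26). Of interleukin-5 and STAT5 response genes 4 of 16 rose (6 adjusted over the list alone, camera adjusted p = 0.0011, and adjusted p = 0.21 with an estimated correlation), with Bcl2l1, an anti-apoptotic gene, at 0.99 (SE 0.16) and the feedback inhibitor Cish at 0.63 (SE 0.13). Adhesion and chemotaxis genes rose in 3 of 18 cases (5 adjusted over the list alone, camera adjusted p = 6.7e-05, and adjusted p = 0.17 with an estimated correlation), with the integrin Itgal at 1.09 (SE 0.16) and the complement receptor C5ar1 at 0.86 (SE 0.14). The call of Cish ended without IL5Tg S7, IL5Tg S8 or IL5Tg S9, or with library totals only (edgeR adjusted p from 0.051 to 0.071). The calls of Bcl2l1 and Cish ended without mdx_IL5Tg S1 (edgeR adjusted p = 0.051 and 0.13). Glycolysis and hypoxia genes called higher numbered 7 without mdx_IL5Tg S1. NF-kB and cytokine genes called higher numbered 5 without IL5Tg S8, IL5Tg S9 or mdx_IL5Tg S2, or with library totals only and 3 without mdx_IL5Tg S1. Type 2 and repair genes called higher numbered 3 without mdx_IL5Tg S1. Interleukin-5 and STAT5 genes called higher numbered 2 without IL5Tg S7 or mdx_IL5Tg S2, 1 without IL5Tg S8 or IL5Tg S9, or with library totals only, 0 without mdx_IL5Tg S1 and 8 without mdx S5, or with voom quality weights. Adhesion and chemotaxis genes called higher numbered 8 without mdx S5, 10 with voom quality weights and 5 with GC offsets, or without IL5Tg S7 and mdx S5 together.

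Some macrophage and phagocyte genes also rose in mdx_IL5Tg. Of macrophage markers 8 of 20 rose (13 adjusted over the list alone, camera adjusted p = 5.9e-08, and adjusted p = 0.35 with an estimated correlation), with C1qb at 3.25 (SE 0.67) and the mannose receptor Mrc1 at 2.31 (SE 0.44). In mdx_IL5Tg S3 C1qb was at 2.38 CPM, against 11.2 and 15.5 in S1 and S2. In the phagocyte list linked to Trem2 5 of 20 rose (10 adjusted over the list alone, camera adjusted p = 7.5e-10, and adjusted p = 0.19 with an estimated correlation), among them Gpnmb at 5.21 (SE 0.55) and Itgax, which encodes CD11c, at 2.30 (SE 0.18). Lysosome genes rose in 7 of 20 cases (8 adjusted over the list alone, camera adjusted p = 1.7e-06, and adjusted p = 0.21 with an estimated correlation), with the protease Ctss at 4.40 (SE 0.66). Class II and dendritic cell genes rose in 5 of 12 cases (6 adjusted over the list alone, camera adjusted p = 1.1e-04, and adjusted p = 0.35 with an estimated correlation), with Cd74 at 2.62 (SE 0.44), H2-Aa at 2.96, H2-Eb1 at 3.20 and H2-Ab1 at 2.73. The sort had excluded cells positive for CD11c or MHC class II. Mmp19, a matrix protease, rose by 3.63 (SE 0.47) and the imprinted RNA H19 by 3.41 (SE 0.49). Muscle fibre genes rose in 7 of 18 cases and Dmd fell by 1.40 (12 adjusted over the list alone, camera adjusted p = 1.4e-07, and adjusted p = 0.29 with an estimated correlation), with Acta1, skeletal actin, going from 1.57 ± 0.238 to 5.67 ± 0.921 CPM. The calls of C1qb, H2-Ab1 and Mrc1 ended without IL5Tg S7, or without IL5Tg S7 and mdx S5 together (edgeR adjusted p from 0.052 to 0.073). The calls of C1qb, H2-Ab1, H2-Eb1 and Mrc1 ended without IL5Tg S8 (edgeR adjusted p from 0.053 to 0.077). The calls of H2-Aa, H2-Ab1 and H2-Eb1 ended without IL5Tg S9 (edgeR adjusted p = 0.063, 0.065 and 0.076). The calls of C1qb, H2-Aa, H2-Ab1, H2-Eb1 and Mrc1 ended without mdx_IL5Tg S1 (edgeR adjusted p from 0.077 to 0.12). The calls of C1qb, H2-Aa, H2-Ab1 and H2-Eb1 ended without mdx_IL5Tg S2, or with no filter (edgeR adjusted p from 0.073 to 0.10). The calls of C1qb, H2-Ab1 and H2-Eb1 ended with limma voom (adjusted p = 0.084, 0.051 and 0.074). The calls of C1qb and H19 ended with voom quality weights (adjusted p = 0.060 and 0.056). Without IL5Tg S7, H2-Eb1 was at 3.91. Macrophage genes called higher numbered 1 without IL5Tg S7, IL5Tg S8 or mdx_IL5Tg S2, 3 without IL5Tg S9, or with limma voom, 0 without mdx_IL5Tg S1 and 5 without IL5Tg S7 and mdx S5 together. Phagocyte genes called higher numbered 3 without IL5Tg S7 or mdx_IL5Tg S2, 2 without mdx_IL5Tg S1, 8 without mdx_IL5Tg S3 or mdx S5, or with only the groups compared, 9 with DESeq2 and 11 with voom quality weights. Lysosome genes called higher numbered 4 without IL5Tg S7, IL5Tg S8 or mdx_IL5Tg S2 and 3 without mdx_IL5Tg S1. Class II and dendritic cell genes called higher numbered 3 without IL5Tg S7, 2 without IL5Tg S8, or with limma voom or no filter and 1 without IL5Tg S9, mdx_IL5Tg S1 or mdx_IL5Tg S2. Muscle fibre genes called higher numbered 2 without IL5Tg S7, IL5Tg S9 or mdx_IL5Tg S1 and 3 without mdx_IL5Tg S2, or with limma voom. Tested with fry against no change, the macrophage and class II and dendritic cell lists did not pass (fry adjusted p = 0.066 and 0.083).

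Proliferation genes fell in 7 of 21 cases (18 adjusted over the list alone, camera adjusted p = 2.8e-08, and adjusted p = 0.44 with an estimated correlation). Mki67, a marker of cycling cells, went from 111 ± 81.4 to 14.4 ± 4.61 CPM, Rrm2, a subunit of ribonucleotide reductase, fell by 2.48 and the mitotic motor Kif11 by 2.37. The histone genes Hist1h4f, Hist1h3c, Hist2h3c2, Hist1h2ak and Hist1h2ab, which share reads with near-identical copies, changed by -2.61, -2.53, -2.45, -2.43 and -2.33. Gpr141, an orphan receptor, fell by 2.46 (SE 0.35) and Ifitm6 by 2.78. Within IL5Tg, Mki67 stood at 202 CPM in S7, 44.3 in S8 and 87.8 in S9. The granule gene Prg2, chosen after its values were seen, stood at 6997, 1611 and 2690.5 CPM in the same libraries. The calls of Hist1h2ab, Hist1h2ak, Hist1h3c, Hist1h4f, Hist2h3c2, Ifitm6, Kif11, Mki67 and Rrm2 ended without IL5Tg S7, mdx_IL5Tg S1, mdx_IL5Tg S2 or mdx_IL5Tg S3, or with no filter (edgeR adjusted p from 0.053 to 0.16). The calls of Hist1h2ab, Hist1h2ak, Hist1h3c, Hist1h4f, Hist2h3c2, Ifitm6, Kif11 and Mki67 ended without IL5Tg S9 (edgeR adjusted p from 0.052 to 0.063). The call of Mki67 ended without mdx S4 (edgeR adjusted p = 0.059). The calls of Hist1h2ab, Hist1h2ak and Hist1h4f ended with limma voom (adjusted p = 0.062, 0.054 and 0.071). The call of Hist1h2ab ended without IL5Tg S7 and mdx S5 together (edgeR adjusted p = 0.055). Without IL5Tg S7, Hist1h2ab was at -1.44, Hist1h2ak was at -1.53, Hist1h3c was at -1.68, Hist1h4f was at -1.49, Hist2h3c2 was at -1.47, Ifitm6 was at -1.93, Kif11 was at -1.54 and Rrm2 was at -1.50. Proliferation genes called lower numbered 1 without IL5Tg S7 or mdx_IL5Tg S2, 15 without IL5Tg S8, 3 without IL5Tg S9, 0 without mdx_IL5Tg S1, 2 without mdx_IL5Tg S3, 4 without mdx S4, 16 with DESeq2 and 11 with voom quality weights. Tested with fry against no change, the proliferation list did not pass (fry adjusted p = 0.12).

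Further lists had fewer calls in mdx_IL5Tg against IL5Tg. Of 12 monocyte genes 1 higher and 2 lower passed, including Ly6c2 at -2.28 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.46). Of 15 neutrophil genes 3 higher passed, including Il1r2 at 2.02 (3 higher adjusted over the list alone, camera adjusted p = 0.53), the list median being -2.01, the mean -1.33 and camera's direction up. Of 10 myoblast genes 1 higher passed, namely Cdh15 at 2.15 (4 higher adjusted over the list alone, camera adjusted p = 7.6e-04, and adjusted p = 0.44 with an estimated correlation), but 0 higher and 0 lower with library totals only and 0 higher and 0 lower with GC offsets. Of 16 matrix genes 1 higher passed, namely Gsn at 0.95 (1 higher adjusted over the list alone, camera adjusted p = 0.025, and adjusted p = 0.76 with an estimated correlation). Of 21 immediate early and stress genes 1 higher passed, namely Egr2 at 1.57 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.14), but 1 higher and 1 lower with library totals only. Of 8 mast cell and basophil genes 1 lower passed, namely Ms4a2 at -3.98 (1 lower adjusted over the list alone, camera adjusted p = 0.26), but 0 higher and 0 lower with GC offsets. No member of 10 lists passed in edgeR over all genes. Their numbers tested, past an unadjusted p of 0.05 and past the threshold with DESeq2 were, in this order, eosinophil 18, 12 and 8 (adjusted over the list alone, 5 higher and 3 lower), interferon-stimulated 20, 1 and 0, cholesterol synthesis 16, 7 and 3, nuclear oxidative phosphorylation 20, 6 and 1, B cell 8, 1 and 1. For the others they were T and NK cell 6, 2 and 1 (adjusted over the list alone, 1 lower), endothelial 12, 1 and 1, erythroid and platelet 9, 0 and 0, ribosomal protein 22, 0 and 0, mitochondrially encoded 13, 1 and 0. Camera called nuclear oxidative phosphorylation genes higher (adjusted p = 6.2e-04, and adjusted p = 0.61 with an estimated correlation) and cholesterol synthesis genes lower (adjusted p = 0.049, and adjusted p = 0.69 with an estimated correlation). Camera called none of the other 8, and the eosinophil list had a median of 0.20, a mean of -0.62 and the direction up in camera. The calls of Cdh15, Gsn, Ly6c2 and Ms4a2 ended without IL5Tg S7, mdx_IL5Tg S1 or mdx_IL5Tg S2 (edgeR adjusted p from 0.063 to 0.20). The calls of Cdh15, Gsn and Ms4a2 ended without IL5Tg S8 (edgeR adjusted p = 0.098, 0.062 and 0.084). The calls of Cdh15 and Ms4a2 ended without IL5Tg S9 or mdx S6, or with limma voom or GC offsets (adjusted p from 0.051 to 0.073). The calls of Ly6c2 and Ms4a2 ended without mdx_IL5Tg S3 (edgeR adjusted p = 0.065 and 0.051). The calls of Cdh15, Ly6c2 and Ms4a2 ended without mdx S4 (edgeR adjusted p = 0.054, 0.050 and 0.062). The call of Cdh15 ended with library totals only or only the groups compared (edgeR adjusted p = 0.066 and 0.064). The call of Ly6c2 ended with no filter (edgeR adjusted p = 0.11). The call of Ms4a2 ended without IL5Tg S7 and mdx S5 together (edgeR adjusted p = 0.054). Without IL5Tg S7, Cdh15 was at 2.81, Ly6c2 was at -1.60 and Ms4a2 was at -2.84. Neutrophil genes called higher numbered 1 without IL5Tg S7, mdx_IL5Tg S1 or mdx_IL5Tg S2. The matrix list lost its camera call without IL5Tg S7, IL5Tg S8 or mdx_IL5Tg S2, with voom quality weights or the stricter filter, or without IL5Tg S7 and mdx S5 together (adjusted p from 0.053 to 0.63). The cholesterol synthesis list lost its camera call without IL5Tg S7, IL5Tg S9, mdx_IL5Tg S2, mdx_IL5Tg S3, mdx S4, mdx S5 or mdx S6, or without IL5Tg S7 and mdx S5 together (adjusted p from 0.054 to 0.29). Tested with fry against no change, the myoblast, matrix, cholesterol synthesis and nuclear oxidative phosphorylation lists did not pass (fry adjusted p = 0.096, 0.41, 0.12 and 0.12).

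The comparison of mdx with mdx_IL5Tg asked how cells sorted as eosinophils from dystrophic muscle differed without and with the transgene. In mdx, glycolysis and hypoxia genes and named survival and eosinophil genes were lower. Higher were 14 of 20 interferon-stimulated, 17 of 20 macrophage, 12 of 16 matrix (2 lower) and 13 of 18 muscle fibre genes (1 lower). Interferon-stimulated calls numbered 1, 2 and 2 without mdx_IL5Tg S1, S3 or mdx S4. Macrophage calls there numbered 6, 11 and 5, and matrix calls 1, 4 and 3. Muscle fibre calls numbered 6, 8, 8 and 6 without mdx_IL5Tg S1, S2, S3 or mdx S4, and interferon-stimulated calls 8 without mdx S6. With no filter macrophage and matrix calls numbered 11 and 5, and with only the groups compared muscle fibre calls 8. Bcl2l1 fell from 148 ± 9.69 to 22.6 ± 4.83 CPM, and Siglecf, which encodes the surface lectin used for the sort, from 520.4 ± 67.8 to 157 ± 24.7 CPM (SD, n = 3). In edgeR 3433 genes changed, 1830 higher and 1603 lower in mdx. The groups did not overlap in 41.99% of genes, against 10% by chance. Genes called higher and lower numbered 1179 and 1756 without IL5Tg S9, 429 and 1092 without mdx_IL5Tg S1 and 945 and 1557 without mdx_IL5Tg S3. They numbered 600 and 1282 without mdx S4 and 916 and 1442 without mdx S6. Of the changed genes 53.3% were higher, and this split moved with the scaling and the libraries used. The share was 84.3% with library totals only. Most changed genes were lower in other alternatives, the higher share in mdx against mdx_IL5Tg being 48.6% with RLE factors, 39.8% with only the groups compared, 48.0% without IL5Tg S7 and mdx S5 together, 42.2% with GC offsets, 39.7% without IL5Tg S7, 41.1% without IL5Tg S8, 40.2% without IL5Tg S9, 28.2% without mdx_IL5Tg S1, 37.8% without mdx_IL5Tg S3, 31.9% without mdx S4 and 38.8% without mdx S6. With library totals only the median log2 change of all genes went from 0.13 to 0.46.

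Glycolysis and hypoxia genes fell in 17 of 18 cases (17 adjusted over the list alone, camera adjusted p = 5.1e-21, and adjusted p = 0.17 with an estimated correlation). Ldha, lactate dehydrogenase A, went from 1162 ± 154 to 403 ± 37.5 CPM, Gapdh fell by 1.51, Egln3 by 1.94 and Bnip3 by 2.06. Of interleukin-5 and STAT5 response genes 6 of 16 fell and 1 rose (6 and 2 adjusted over the list alone, camera adjusted p = 3.8e-05, and adjusted p = 0.17 with an estimated correlation). Socs2, a STAT5-induced feedback inhibitor, changed by -2.77 (SE 0.13, edgeR adjusted p = 8.5e-07), Bcl2l1 by -2.71 (SE 0.17), the cytokine Osm by -1.47 (SE 0.17) and Cish by -0.81 (SE 0.14). Eosinophil genes fell in 5 of 18 cases (5 adjusted over the list alone, camera adjusted p = 6.1e-07, and adjusted p = 0.12 with an estimated correlation), with Il1rl1, the interleukin-33 receptor, going from 1574 ± 144 to 393 ± 30.1 CPM and the lipoxygenase Alox15 changing by -1.39 (SE 0.25). Of type 2 and repair mediators, Il5 included, 5 of 15 fell and 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 8.3e-05, and adjusted p = 0.17 with an estimated correlation). The median of that list was 0.30, its mean -0.41 and camera's direction down. That camera call rested on the transgene and ended without Il5, left out after seeing the data, where 4 of 14 fell and 2 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.20), with a median of 0.42 and a mean of 0.34. The cytokines Il4 and Il13 fell by 1.28 and 1.73 and Vegfa by 1.69. Cholesterol synthesis genes fell in 7 of 16 cases (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.0e-04, and adjusted p = 0.38 with an estimated correlation), although 2 fell and 2 rose with library totals only. Msmo1, an enzyme of that pathway, fell by 0.95. Eosinophil genes called lower numbered 10 without mdx S6, or with voom quality weights, 3 with library totals only, 9 with DESeq2 or limma voom and 8 with only the groups compared. The type 2 and repair list lost its camera call with limma voom or voom quality weights (adjusted p = 0.15 and 0.22). Cholesterol synthesis genes called lower numbered 3 without mdx_IL5Tg S1, 4 without mdx S4 and 2 with library totals only.

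The 10 largest falls under the naming rule included Il5, at -11.03 (SE 0.29), and genes nearly silent in mdx. Cmtm2a and Cmtm1, overlapping genes whose reads cannot be fully told apart, had at most 4 and 4 counts in any mdx library, against 15.8 ± 4.07 and 14.5 ± 3.48 CPM in mdx_IL5Tg. Crhbp, which binds corticotropin-releasing hormone, went from 19.8 ± 1.97 to 0.128 ± 0.0688 CPM and the cell-cycle inhibitor Cdkn2a from 29.1 ± 6.89 to 0.273 ± 0.153 CPM. Cyp11a1, which starts steroid hormone synthesis, went from 56.0 ± 8.02 to 0.759 ± 0.200 CPM. Car4, a carbonic anhydrase, changed by -5.77 (SE 0.22), the potassium channel gene Kcnk5 by -5.29 (SE 0.29), Aifm3 by -4.62 (SE 0.28) and Upp1, a uridine phosphorylase, by -4.39 (SE 0.15).

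Interferon-stimulated genes rose in mdx in 14 of 20 cases (17 adjusted over the list alone, camera adjusted p = 1.0e-05, and adjusted p = 0.44 with an estimated correlation), among them Oasl1 at 2.39 (SE 0.39) and Ifit2 at 1.78 (SE 0.39). Macrophage markers rose in 17 of 20 cases (18 adjusted over the list alone, camera adjusted p = 2.9e-08, and adjusted p = 0.29 with an estimated correlation), with the Fc receptor Fcgr1 at 2.24 (SE 0.42). In the phagocyte list linked to Trem2 10 of 20 rose and 5 fell (10 and 6 adjusted over the list alone, camera adjusted p = 0.27). Its members Apoe, Gpnmb and Lpl rose by 2.76, 2.64 and 1.94, and Cst7, a protease inhibitor, fell by 2.09. Spp1, osteopontin, went from 30.8 ± 24.0 to 245 ± 156 CPM, F13a1 rose by 2.55 (SE 0.50) and Ctss by 2.72 (SE 0.56). Matrix genes rose in 12 of 16 cases and fell in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 4.0e-04, and adjusted p = 0.55 with an estimated correlation). The growth factor receptor Pdgfra rose by 1.94 (SE 0.40), Gsn and Pi16 fell by 1.04 and 1.16, and Col11a1, a fibrillar collagen, rose by 2.54 (SE 0.42). Muscle fibre genes rose in 13 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 1.2e-04, and adjusted p = 0.44 with an estimated correlation), with Ttn, titin, at 3.15 (SE 0.45) and Neb, nebulin, lower at -2.77 (SE 0.35). Myoblast markers rose in 7 of 10 cases (8 adjusted over the list alone, camera adjusted p = 4.5e-04, and adjusted p = 0.39 with an estimated correlation), with Chodl at 1.97 (SE 0.41). Sel1l3, Slfn8 and the imprinted RNA Meg3 completed the largest rises, at 3.50 (SE 0.21), 3.00 (SE 0.58) and 2.93 (SE 0.33). The calls of Ifit2 and Spp1 ended without mdx_IL5Tg S1 (edgeR adjusted p = 0.058 and 0.054). Without mdx S4, Fcgr1 was at 1.47 and Ttn was at 2.48. Interferon-stimulated genes called higher numbered 1 without mdx_IL5Tg S1, 2 without mdx_IL5Tg S3 or mdx S4 and 8 without mdx S6. Macrophage genes called higher numbered 6 without mdx_IL5Tg S1, 11 without mdx_IL5Tg S3, or with no filter and 5 without mdx S4. Phagocyte genes called higher numbered 6 without mdx_IL5Tg S1. Phagocyte genes called lower numbered 3 without mdx_IL5Tg S1, 2 with library totals only and 8 with voom quality weights. Matrix genes called higher numbered 1 without mdx_IL5Tg S1, 4 without mdx_IL5Tg S3, 3 without mdx S4 and 5 with no filter. Muscle fibre genes called higher numbered 6 without mdx_IL5Tg S1 or mdx S4 and 8 without mdx_IL5Tg S2 or mdx_IL5Tg S3, or with only the groups compared. Myoblast genes called higher numbered 1 without mdx_IL5Tg S1, 4 without mdx_IL5Tg S3 or mdx S6 and 2 of 9 tested without mdx S4. Tested with fry against no change, the matrix list did not pass (fry adjusted p = 0.056).

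Other lists changed in fewer members in mdx against mdx_IL5Tg. Of 20 NF-kB and cytokine genes 4 higher and 3 lower passed, including Nlrp3 at 2.95 and Icam1 at 1.26 (5 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.82), but 4 higher and 5 lower with GC offsets, the list median being -0.10, the mean 0.18 and camera's direction down. Of 18 adhesion and chemotaxis genes 3 higher and 7 lower passed, including Itgam at -0.73 and Selplg at -0.71 (3 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.35 with an estimated correlation), the list median being -0.43, the mean 0.099 and camera's direction down. Of 20 lysosome genes 2 higher and 7 lower passed, including Ctsh at -1.22 and Ctss at 2.72 (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.63 with an estimated correlation), but 4 higher and 1 lower with library totals only. Of 21 immediate early and stress genes 2 higher and 5 lower passed, including Fos at -1.31 and Fosb at -1.03 (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.14), but 4 higher and 2 lower with library totals only. Of 12 class II and dendritic cell genes 2 higher and 1 lower passed, including Cd80 at -1.31 (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.094). Of 12 monocyte genes 7 higher and 2 lower passed, including Plac8 at -1.12 and F13a1 at 2.55 (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.13). Of 15 neutrophil genes 2 higher and 2 lower passed, including Cxcr2 at -3.26 and Il1r2 at -2.51 (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.094), the list median being 0.97, the mean 0.36 and camera's direction down. Of 8 B cell genes 2 higher passed, including Ebf1 at 1.06 (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.99), the list median being -0.24, the mean -0.19 and camera's direction up. Of 6 T and NK cell genes 1 higher and 1 lower passed, namely Cd3d at -2.90 and Il7r at 2.25 (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.81), where Cd3d counts may come from the transgene construct, whose sequence the labels do not give. Of 8 mast cell and basophil genes 3 higher passed, including Mcpt4 at 3.45 (5 higher adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.58 with an estimated correlation). Of 9 erythroid and platelet genes 1 lower passed, namely Itga2b at -0.91 (1 lower adjusted over the list alone, camera adjusted p = 0.99), but 0 higher and 0 lower with library totals only, the list median being 0.15, the mean 0.27 and camera's direction down. Of 12 endothelial genes 1 higher passed, namely Kdr at 1.22 (7 higher adjusted over the list alone, camera adjusted p = 0.010, and adjusted p = 0.69 with an estimated correlation). Of 21 proliferation genes 1 higher passed, namely Tyms at 1.63 (no member adjusted over the list alone, camera adjusted p = 0.14), but 1 higher and 1 lower with GC offsets. Of 20 nuclear oxidative phosphorylation genes 5 lower passed, including Ndufa1 at -1.01 and Cox5a at -0.92 (6 lower adjusted over the list alone, camera adjusted p = 0.010, and adjusted p = 0.74 with an estimated correlation). Of 22 ribosomal protein genes 2 lower passed, including Rpl10 at -0.46 (no member adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.76 with an estimated correlation), but 0 higher and 0 lower with library totals only. No mitochondrially encoded gene passed in edgeR (tested, past an unadjusted p of 0.05 and past the threshold with DESeq2: 13, 1 and 1; camera adjusted p = 0.060). The call of Tyms ended without IL5Tg S9 (edgeR adjusted p = 0.055). The calls of Ebf1, Itga2b, Kdr, Rpl10 and Tyms ended without mdx_IL5Tg S1 (edgeR adjusted p from 0.065 to 0.15). The call of Rpl10 ended without mdx_IL5Tg S2, or with no filter or the stricter filter (edgeR adjusted p = 0.063, 0.056 and 0.054). The calls of Ebf1 and Tyms ended without mdx_IL5Tg S3 (edgeR adjusted p = 0.063 and 0.11). The calls of Ebf1, Mcpt4, Rpl10 and Tyms ended without mdx S4 (edgeR adjusted p from 0.062 to 0.12). The calls of Ebf1, Rpl10 and Tyms ended without mdx S6 (edgeR adjusted p = 0.062, 0.094 and 0.087). The calls of Itga2b and Rpl10 ended with library totals only (edgeR adjusted p = 0.053 and 0.44). Without mdx S4, Il7r was at 1.60 and Mcpt4 was at 2.12. Without mdx_IL5Tg S1, Mcpt4 was at 4.90. NF-kB and cytokine genes called higher numbered 2 without IL5Tg S7, IL5Tg S8, IL5Tg S9, mdx_IL5Tg S1, mdx_IL5Tg S3 or mdx S4, or with only the groups compared. NF-kB and cytokine genes called lower numbered 6 without IL5Tg S8, or with DESeq2, 1 without mdx_IL5Tg S1 or mdx S4, or with library totals only and 5 with GC offsets. Adhesion and chemotaxis genes called higher numbered 1 without mdx_IL5Tg S1. Adhesion and chemotaxis genes called lower numbered 4 with library totals only. Lysosome genes called lower numbered 2 without mdx_IL5Tg S1, 4 without mdx S5 or mdx S6 and 1 with library totals only. The lysosome list lost its camera call without mdx S5 or mdx S6, with library totals only or the stricter filter, or without IL5Tg S7 and mdx S5 together (adjusted p from 0.055 to 0.16). Immediate early and stress genes called lower numbered 3 without mdx_IL5Tg S1, mdx_IL5Tg S3, mdx S4 or mdx S6, or with the stricter filter and 2 with library totals only. Monocyte genes called higher numbered 4 without mdx_IL5Tg S1 and 3 without mdx S4. Mast cell and basophil genes called higher numbered 1 without mdx_IL5Tg S1 or mdx_IL5Tg S3, or with limma voom, 0 without mdx S4, 5 without mdx S5, with library totals only, or without IL5Tg S7 and mdx S5 together and 0 of 2 tested with the stricter filter. The mast cell and basophil list lost its camera call without mdx_IL5Tg S2, or with library totals only or limma voom (adjusted p = 0.062, 0.19 and 0.062). The endothelial list lost its camera call without mdx_IL5Tg S3 (adjusted p = 0.12). Nuclear oxidative phosphorylation genes called lower numbered 9 without mdx S5, 3 with library totals only, 11 with voom quality weights and 10 without IL5Tg S7 and mdx S5 together. The nuclear oxidative phosphorylation list lost its camera call without mdx S6 (adjusted p = 0.062). The ribosomal protein list lost its camera call without mdx_IL5Tg S1 or mdx S6, or with library totals only or the stricter filter (adjusted p from 0.059 to 0.080). Tested with fry against no change, the lysosome, mast cell and basophil, endothelial, nuclear oxidative phosphorylation and ribosomal protein lists did not pass (fry adjusted p = 0.086, 0.066, 0.11, 0.14 and 0.28).

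**Figure D3:**
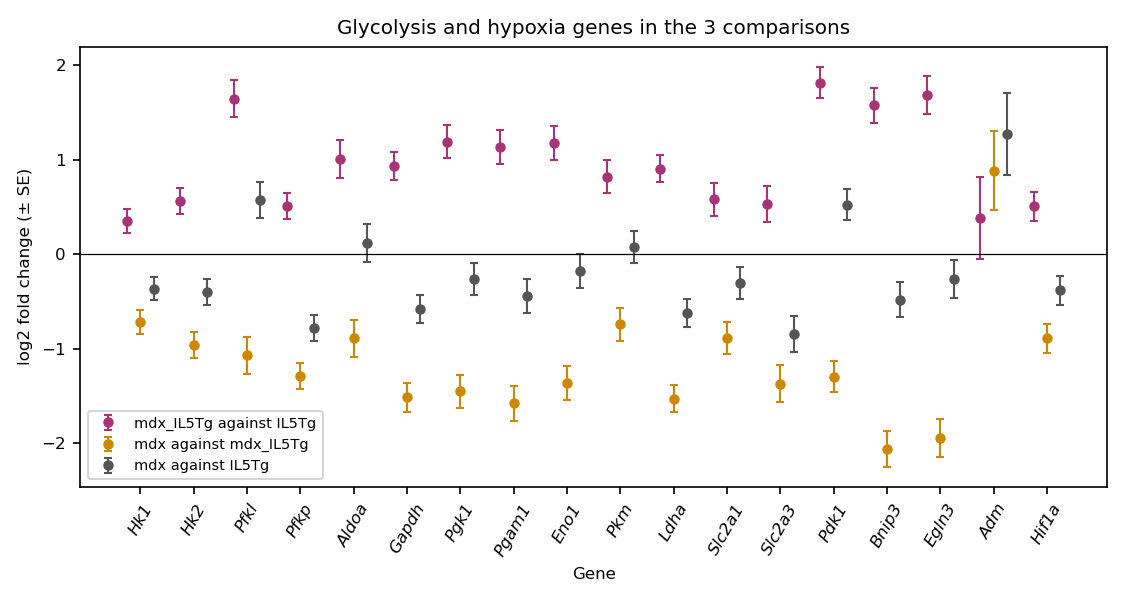
Log2 fold changes with standard errors of the 18 tested glycolysis and hypoxia genes in the 3 comparisons. In mdx_IL5Tg against IL5Tg 13 genes rose, and in mdx against mdx_IL5Tg 17 fell.

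The comparison of mdx with IL5Tg set groups against each other that differ in muscle background and transgene. In mdx, 17 of 20 macrophage, 11 of 16 matrix and 12 of 20 interferon-stimulated genes rose. So did 7 of 12 class II and dendritic cell and 16 of 18 muscle fibre genes (1 each fell). Named granule and 10 of 16 cholesterol synthesis genes fell. Interferon-stimulated calls numbered 4 without IL5Tg S8 or S9 and 5 without mdx S4, and matrix calls 7 without IL5Tg S7 or mdx S4. Granule genes Ear1, Ear2 and Ear6 lost their calls without mdx S4 or with only the groups compared. Prg2 did in the latter and Ear1 also with no filter. Cholesterol synthesis calls numbered 6 without IL5Tg S9 or mdx S6, or with library totals only. Gpnmb (chromosome 6, 49036546 to 49070929), a lysosomal glycoprotein gene, rose from 0.628 ± 0.348 to 145 ± 64.0 CPM, and Il1rl1 fell from 1361 ± 290.3 to 393 ± 30.1 CPM (SD, n = 3). In edgeR 3298 of 15886 genes changed, 1874 higher and 1424 lower in mdx. The groups did not overlap in 41.9% of genes, against 10% by chance. Genes called higher and lower numbered 1245 and 1380 without IL5Tg S7, 975 and 1156 without IL5Tg S8, 948 and 1013 without IL5Tg S9 and 1149 and 1071 without mdx S4. Of the changed genes 56.8% were higher, and this split moved with the scaling and the libraries used. The share was 70.7% with library totals only. Most changed genes were lower in other alternatives, the higher share in mdx against IL5Tg being 48.5% with GC offsets, 47.4% without IL5Tg S7, 45.8% without IL5Tg S8, 48.3% without IL5Tg S9, 49.4% without mdx_IL5Tg S1 and 49.5% without mdx_IL5Tg S3. With library totals only the median log2 change of all genes went from 0.013 to 0.12.

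Macrophage markers rose in 17 of 20 cases (20 adjusted over the list alone, camera adjusted p = 7.5e-19, and adjusted p = 0.17 with an estimated correlation). The complement genes C1qa, C1qb and C1qc rose by 4.79, 5.47 and 4.87, Mrc1 by 3.99 and Cd14, a lipopolysaccharide co-receptor, by 2.70 (SE 0.29). In the phagocyte list linked to Trem2 12 of 20 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 5.1e-08, and adjusted p = 0.21 with an estimated correlation), with Gpnmb at 7.86 (SE 0.59, edgeR adjusted p = 1.9e-05), Apoe at 4.35 (SE 0.49) and the protease Ctsb at 2.53 (SE 0.31). Class II and dendritic cell genes rose in 7 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 2.5e-05, and adjusted p = 0.30 with an estimated correlation), with H2-Eb1 at 4.70 and Cd74 at 3.96 (SE 0.46). Ctss rose by 7.12, Mmp19 by 5.98, Col22a1 by 6.97, H19 by 4.99 and Spp1 by 4.40. Without IL5Tg S9, C1qc was at 6.05. Without mdx S4, H19 was at 4.30 and Spp1 was at 3.72. Without IL5Tg S7, H2-Eb1 was at 5.32.

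Muscle fibre genes rose in 16 of 18 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 6.0e-13, and adjusted p = 0.19 with an estimated correlation), with Acta1 at 3.08 (SE 0.31) and Ttn at 4.27 (SE 0.48). Myoblast markers rose in 9 of 10 cases (9 adjusted over the list alone, camera adjusted p = 4.4e-08, and adjusted p = 0.21 with an estimated correlation), with the muscle regulators Myod1 and Myog at 2.48 (SE 0.42) and 3.58 (SE 0.54). Matrix genes rose in 11 of 16 cases (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.6e-07, and adjusted p = 0.35 with an estimated correlation), among them the collagen gene Col3a1, from 161 ± 76.5 to 1559 ± 651 CPM, and Postn, periostin, at 3.43 (SE 0.49). Interferon-stimulated genes rose in 12 of 20 cases (13 adjusted over the list alone, camera adjusted p = 3.6e-06, and adjusted p = 0.42 with an estimated correlation), with Oasl1 at 2.86 (SE 0.40), Rsad2 at 1.80 (SE 0.33) and the regulator Irf7 at 0.91 (SE 0.17). Of NF-kB and cytokine genes 10 of 20 rose (11 adjusted over the list alone, camera adjusted p = 1.5e-05, and adjusted p = 0.19 with an estimated correlation), with the inflammasome sensor Nlrp3 at 4.15 (SE 0.50) and Nfkbia at 1.51 (SE 0.25). Without mdx S4, Ttn was at 3.65. Matrix genes called higher numbered 7 without IL5Tg S7 or mdx S4, or without IL5Tg S7 and mdx S5 together. Interferon-stimulated genes called higher numbered 4 without IL5Tg S8 or IL5Tg S9 and 5 without mdx S4.

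Eosinophil genes fell in 8 of 18 cases (8 adjusted over the list alone, camera adjusted p = 7.6e-05, and adjusted p = 0.14 with an estimated correlation), among them Siglecf at -1.17 (SE 0.16) and Prg2, the granule major basic protein gene, which went from 3766 ± 2849.9 to 226 ± 239.8 CPM. Prg2 ranged from 1611 CPM in IL5Tg S8 to 6997 in IL5Tg S7 and from 79.3 in mdx S4 to 503 in mdx S6. The eosinophil ribonuclease genes Ear1, Ear2 and Ear6, near-identical paralogs whose reads are shared, fell by 5.25, 5.29 and 4.92. Cholesterol synthesis genes fell in 10 of 16 cases (11 adjusted over the list alone, camera adjusted p = 5.0e-07, and adjusted p = 0.22 with an estimated correlation), with Sqle at -1.79 (SE 0.26) and Msmo1 at -1.45 (SE 0.16). Of interleukin-5 and STAT5 response genes 4 of 16 fell and 3 rose (4 and 6 adjusted over the list alone, camera adjusted p = 0.10), while 4 fell and 5 rose with library totals only. The median of that list was 0.44, its mean -0.13 and camera's direction down, and Socs2, Bcl2l1 and Osm fell by 2.39, 1.72 and 1.31. Il5 changed by -10.35 (SE 0.28). Crhbp went from 30.2 ± 4.14 to 0.128 ± 0.0688 CPM, Cyp11a1 from 87.1 ± 9.17 to 0.759 ± 0.200 CPM, Cdkn2a from 23.5 ± 5.65 to 0.273 ± 0.153 CPM and the lipase gene Lipg from 49.6 ± 38.6 to 1.75 ± 0.391 CPM. Cmtm1 and Cmtm2a were at 9.58 ± 2.90 and 11.1 ± 3.43 CPM in IL5Tg, against at most 4 and 4 counts in any mdx library. The call of Ear1 ended without mdx_IL5Tg S2 or mdx_IL5Tg S3, or with no filter (edgeR adjusted p = 0.056, 0.058 and 0.074). The calls of Ear1, Ear2 and Ear6 ended without mdx S4 (edgeR adjusted p = 0.069, 0.053 and 0.053). The calls of Ear1, Ear2, Ear6 and Prg2 ended with only the groups compared (edgeR adjusted p from 0.053 to 0.095). Without IL5Tg S7, Ear1 was at -4.60 and Ear2 was at -4.53. Without mdx S6, Ear1 was at -7.96, Ear2 was at -7.41 and Ear6 was at -6.96. Eosinophil genes called lower numbered 5 without mdx_IL5Tg S2 or mdx_IL5Tg S3, 3 without mdx S4 and 2 with only the groups compared. Cholesterol synthesis genes called lower numbered 6 without IL5Tg S9 or mdx S6, or with library totals only. Interleukin-5 and STAT5 genes called higher numbered 1 without IL5Tg S7, IL5Tg S8, mdx_IL5Tg S1, mdx_IL5Tg S2 or mdx S6, 0 without IL5Tg S9, or with GC offsets and 5 with library totals only, voom quality weights or no filter.

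The remaining lists in mdx against IL5Tg follow. Of 18 glycolysis and hypoxia genes 1 higher and 4 lower passed, including Pfkp at -0.78 (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.054). Of 15 type 2 and repair genes 8 higher and 3 lower passed, including Il4 at -1.39 and Il5 at -10.35 (8 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.81), the list median being 0.99, the mean 0.53 and camera's direction down. Without Il5, the transgene, left out after seeing the data, 8 of 14 were higher and 2 lower (8 and 3 adjusted over the list alone), with a median of 1.09 and a mean of 1.303, and camera called the list higher (adjusted p = 0.032, and adjusted p = 0.37 with an estimated correlation). Of 18 adhesion and chemotaxis genes 4 higher passed, including Itgal at 0.71 (4 higher adjusted over the list alone, camera adjusted p = 0.68), the list median being -0.045, the mean 0.38 and camera's direction up. Of 20 lysosome genes 6 higher and 3 lower passed, including Psap at 1.48 and Atp6v0d2 at 6.14 (6 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.29), but 4 higher and 4 lower with GC offsets. Of 21 immediate early and stress genes 2 higher and 5 lower passed, including Fos at -1.06 and Egr2 at 2.09 (5 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.79), but 4 higher and 3 lower with library totals only, the list median being -0.11, the mean 0.0029 and camera's direction down. Of 12 monocyte genes 7 higher and 2 lower passed, including Ly6c2 at -3.48 and F13a1 at 3.56 (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.043, and adjusted p = 0.69 with an estimated correlation). Of 15 neutrophil genes 2 higher and 2 lower passed, including Cxcr2 at -1.83 (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.26). Of 8 B cell genes 1 higher and 2 lower passed, including Cd22 at 3.21 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.61), but 1 higher and 1 lower with library totals only. Of 6 T and NK cell genes 2 higher and 2 lower passed, including Cd3d at -3.73 and Il7r at 2.86 (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.91), the list median being 0.61, the mean 0.22 and camera's direction down, where Cd3d counts may come from the transgene construct, whose sequence the labels do not give. Of 8 mast cell and basophil genes 4 higher passed, including Mcpt4 at 3.50 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.37). Of 9 erythroid and platelet genes 1 lower passed, namely Itga2b at -1.29 (1 lower adjusted over the list alone, camera adjusted p = 0.81). Of 12 endothelial genes 4 higher passed, including Kdr at 1.33 and Cldn5 at 2.34 (4 higher adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.76 with an estimated correlation). Of 21 proliferation genes 2 lower passed, including Top2a at -1.56 (2 lower adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.76 with an estimated correlation). Of 20 nuclear oxidative phosphorylation genes 2 higher and 3 lower passed, including Sdha at 0.53 (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.99), but 3 higher and 1 lower with library totals only and 2 higher and 2 lower with GC offsets, the list median being 0.14, the mean 0.046 and camera's direction down. Of 22 ribosomal protein genes 2 lower passed, including Rpl27 at -0.97 (no member adjusted over the list alone, camera adjusted p = 0.11), but 0 higher and 0 lower with library totals only. No mitochondrially encoded gene passed in edgeR (tested, past an unadjusted p of 0.05 and past the threshold with DESeq2: 13, 2 and 1), while camera called that list lower (adjusted p = 0.010, and adjusted p = 0.74 with an estimated correlation). That call was kept without mdx S5, which was low in these transcripts (adjusted p = 0.0081). The calls of Mcpt4, Rpl27 and Top2a ended without IL5Tg S7 (edgeR adjusted p = 0.055, 0.068 and 0.084). The calls of Mcpt4 and Sdha ended without IL5Tg S8 (edgeR adjusted p = 0.067 and 0.071). The calls of Itgal, Mcpt4 and Sdha ended without IL5Tg S9 (edgeR adjusted p = 0.070, 0.078 and 0.060). The calls of Mcpt4 and Top2a ended without mdx S4, or with limma voom (adjusted p from 0.059 to 0.10). The call of Top2a ended without mdx S5, or with no filter or only the groups compared (edgeR adjusted p = 0.11, 0.16 and 0.071). The call of Rpl27 ended with library totals only (edgeR adjusted p = 0.069). The calls of Rpl27 and Top2a ended without IL5Tg S7 and mdx S5 together (edgeR adjusted p = 0.062 and 0.21). Without IL5Tg S9, Atp6v0d2 was at 7.11. Without mdx S4, Atp6v0d2 was at 5.47, Il7r was at 2.25 and Mcpt4 was at 2.20. Without IL5Tg S7, Cd22 was at 3.82 and Top2a was at -0.91. Glycolysis and hypoxia genes called lower numbered 1 without IL5Tg S9, 2 without mdx S4, 7 with DESeq2, 12 with voom quality weights and 9 with GC offsets. Type 2 and repair genes called higher numbered 5 without IL5Tg S8, IL5Tg S9 or mdx S4 and 5 of 11 tested with the stricter filter. Type 2 and repair genes called lower numbered 5 without IL5Tg S7. Adhesion and chemotaxis genes called higher numbered 2 without IL5Tg S9. Lysosome genes called higher numbered 3 without IL5Tg S8 or mdx S4. Lysosome genes called lower numbered 5 without IL5Tg S7. Immediate early and stress genes called lower numbered 2 without IL5Tg S9, 3 without mdx S4 or mdx S6, or with library totals only or only the groups compared, 8 with voom quality weights and 9 with GC offsets. The monocyte list lost its camera call without IL5Tg S8, with library totals only, limma voom, voom quality weights or the stricter filter, or without IL5Tg S7 and mdx S5 together (adjusted p from 0.052 to 0.16). Mast cell and basophil genes called higher numbered 2 without IL5Tg S7, or with voom quality weights, 1 without IL5Tg S8, IL5Tg S9 or mdx S4, or with limma voom and 1 of 2 tested with the stricter filter. Endothelial genes called higher numbered 2 without IL5Tg S8 or IL5Tg S9. The endothelial list lost its camera call without IL5Tg S8 or mdx S6 (adjusted p = 0.11 and 0.062). The proliferation list lost its camera call without IL5Tg S7, or without IL5Tg S7 and mdx S5 together (adjusted p = 0.32 and 0.53). Nuclear oxidative phosphorylation genes called lower numbered 0 without IL5Tg S7, 1 without IL5Tg S9, mdx S4 or mdx S6, or with library totals only and 5 with voom quality weights. The mitochondrially encoded list lost its camera call with DESeq2, voom quality weights or GC offsets (adjusted p = 0.12, 0.071 and 0.16). Tested with fry against no change, the monocyte, endothelial, proliferation and mitochondrially encoded lists did not pass (fry adjusted p = 0.14, 0.19, 0.30 and 0.17).

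**Figure D4:**
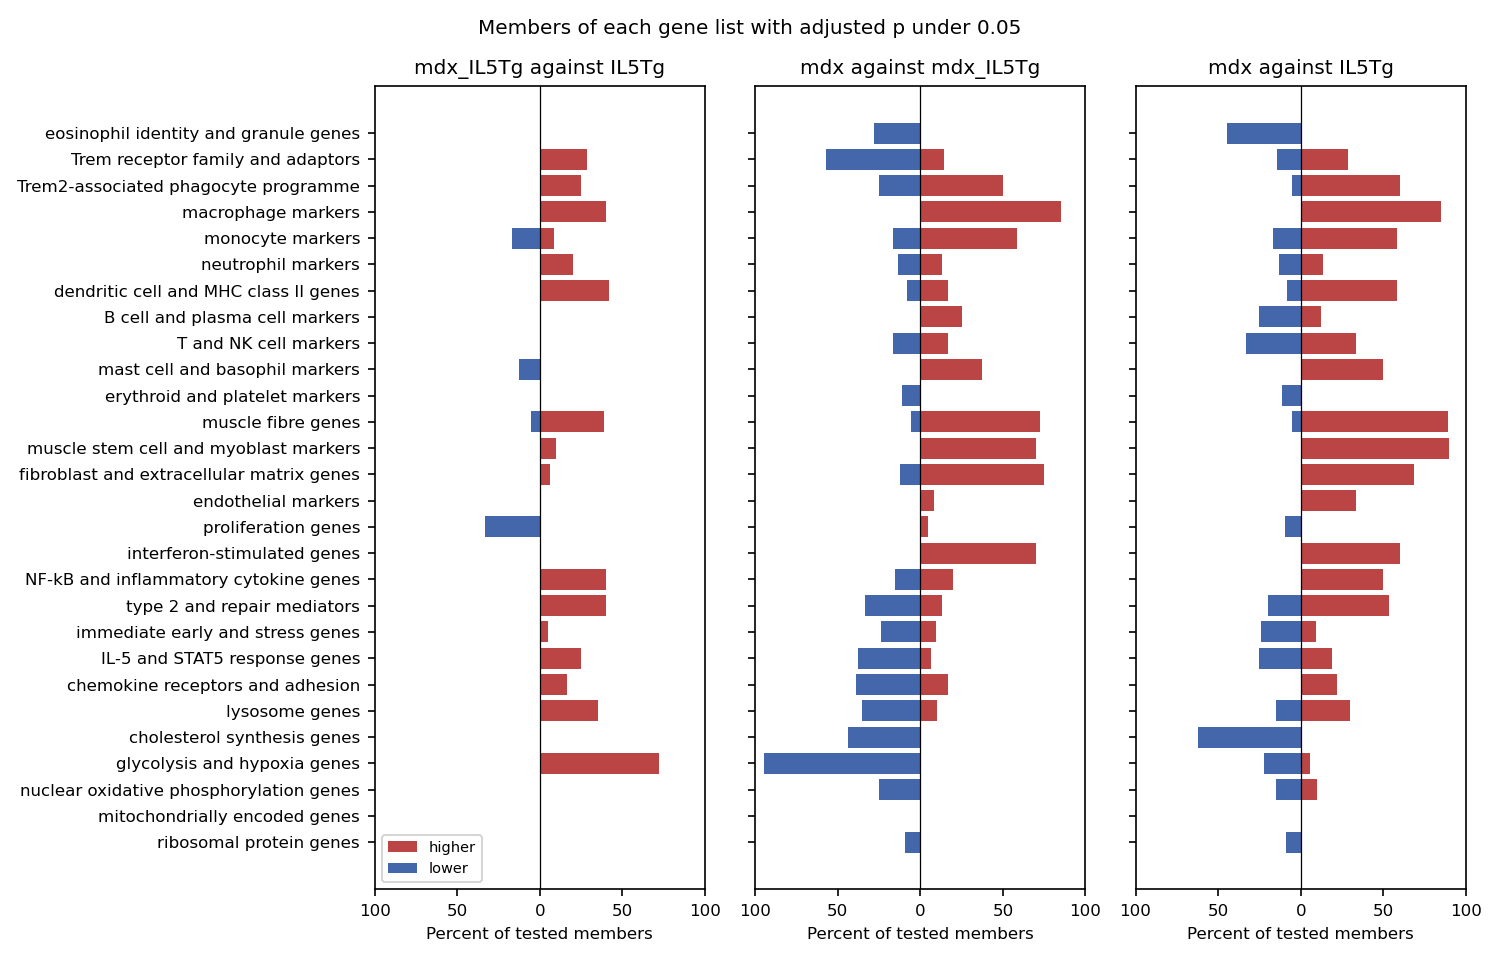
Percent of tested members of each gene list that passed the threshold in each comparison, with bars to the right for higher and to the left for lower. Macrophage markers rose in 8, 17 and 17 of 20 cases from the left panel to the right, and glycolysis and hypoxia genes rose in 13 in the left panel and fell in 17 in the middle one.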

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

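Removing IL5Tg S7 and mdx S5 together, GC offsets and the type 2 and repair list without Il5, the transgene, were alternatives chosen after seeing the data; the others were planned. No paired analysis was possible because the columns carry S numbers and not the replicate numbers of the titles, so the planned block for replicate was not run. The count of changed genes in mdx_IL5Tg against IL5Tg (1147) was 2464 with DESeq2, 4294 with voom quality weights, 1816 with only those groups, 1739 without the 2 libraries, and 110 (without mdx_IL5Tg S1) to 2641 (without mdx S5) with single libraries left out. Voom quality weights gave 6929 genes in mdx against mdx_IL5Tg and 5498 in mdx against IL5Tg, and single libraries left out gave 1521 to 4057 and 1961 to 3837. Fewer libraries lower the power; the cause of the other moves was not tested. With library totals only, the median log2 change of all genes went from -0.050 to -0.27, from 0.13 to 0.46 and from 0.013 to 0.12 in these comparisons, and the share of higher genes from 60.2% to 24.1%, 53.3% to 84.3% and 56.8% to 70.7%. GC offsets gave 42.2% higher in mdx against mdx_IL5Tg.

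Trem2 kept its direction in every alternative run, and its call except in mdx_IL5Tg against IL5Tg with limma voom (3.40) and without IL5Tg S7 (3.40), IL5Tg S9 (3.17) or mdx_IL5Tg S1 (3.52). Over the 9 runs without 1 library its change there ranged from 3.03 to 4.17, and the cause was not tested. Of the called genes fixed for naming, 25 of 67, 73 of 106 and 82 of 115 kept their call in every alternative that tested them, and none of these turned direction. Values that turned were of genes past no threshold; the cause was not tested. In mdx_IL5Tg against IL5Tg, Igkc was at 0.50 with voom quality weights, Hbb-bs was at -0.30 without mdx_IL5Tg S3 and 0.87 without IL5Tg S7, Hba-a1 was at -0.21 without mdx_IL5Tg S3 and 0.80 without mdx_IL5Tg S1 and Hba-a2 was at -0.27 without mdx_IL5Tg S3 and 0.75 without mdx_IL5Tg S1. There, mt-Nd4 was at 0.062 with GC offsets, Rpl3 was at -0.038 with library totals only and Rpl19 was at -0.024 with library totals only. In mdx against mdx_IL5Tg, Treml4 was at -0.043 without mdx S4 and 0.38 without mdx S5, Hba-a2 was at -0.14 without mdx_IL5Tg S1 and 0.88 without mdx_IL5Tg S3 and Alas2 was at -0.21 without mdx S6 and 1.48 without mdx_IL5Tg S3. In mdx against IL5Tg, Hcst was at 0.048 without mdx S4 and -0.36 without mdx S5 and mt-Nd6 was at 0.27 with GC offsets. Without Il5, the type 2 and repair list lost its camera call in mdx against mdx_IL5Tg (adjusted p from 8.3e-05 to 0.20) and turned from down to up in mdx against IL5Tg (from 0.81 to 0.032), the cause being the lack of the transgene in mdx. Depth limits low genes: Trem2 rested on at most 10 counts in an IL5Tg library.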

Other observations

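The tests of gene families and of explanations in this part were chosen after the results were seen; the counts over other splits of the libraries were planned. Genes were grouped by the letters that open their symbols, and families with at least 8 tested members were compared with all other tested genes by one-sided Fisher's exact tests (230 families, 1380 tests, Benjamini-Hochberg). Genes of a family are not independent replicates. Replication-dependent histone genes fell in mdx against IL5Tg in 40 of 61 cases, 65.6% against 8.75% of other genes (Fisher's exact adjusted p = 2.0e-24), and in mdx_IL5Tg against IL5Tg in 17 (Fisher's exact adjusted p = 2.6e-10). These near-identical genes share reads. The counts of histone genes rested on single libraries: 15 without IL5Tg S7, 15 without mdx S4 and 25 without mdx S5 in the former comparison and 0 without IL5Tg S7, 28 without IL5Tg S8, 0 without IL5Tg S9, 0 without mdx_IL5Tg S1, 0 without mdx_IL5Tg S2, 3 without mdx_IL5Tg S3, 11 without mdx S4 and 26 without mdx S5 in the latter. Collagen genes rose in mdx against mdx_IL5Tg in 27 of 41 cases and against IL5Tg in 26 (Fisher's exact adjusted p = 1.8e-13 and 3.1e-12). The former count was 8 without mdx_IL5Tg S1 and 12 without mdx S4, and no single library moved the latter by over 1.5 times. Matrix metalloproteinase genes rose in 10 of 16 cases in mdx against IL5Tg (Fisher's exact adjusted p = 3.6e-04), 6 without IL5Tg S8 and 6 without mdx S4. With library totals only the histone counts were 35 and 21, those of collagen 32 and 26 and that of metalloproteinases 10.

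Trem2 was higher in mdx libraries along with macrophage transcripts, and a lower share of eosinophil RNA that raised every other cell type alike is argued against: macrophage markers under 5 CPM in IL5Tg rose in the median by 4.13, 13 of 16 past the threshold, against -0.020 for 19 markers of B, T, NK and mast cells, 6 of them higher and 3 lower past the threshold, a difference of 4.15 (bootstrap SE 1.08); no endothelial marker was that low. Yet Cma1, Cd4, Mcpt4, Cd22 and Tpsb2 among the others rose by 4.12, 3.55, 3.50, 3.21 and 3.00, as far as macrophage genes, and muscle and matrix lists rose as well, so a lower share with uneven changes of other cells stays open; library scaling alone is argued against, since Trem2 stayed at 5.95 with library totals only. RNA of macrophages in the sorted cells remains a candidate source: all 7 of C1qa, C1qb, C1qc, Mrc1, Lyz2, Apoe and Cd68 rose in mdx against IL5Tg, by 2.19 to 5.47, and the ratio of Trem2 to C1qb differed by 2.12-fold between the 6 libraries with the mdx background, while in IL5Tg, at 2 to 10 Trem2 counts, it ran from 0.0488 to 0.769. Of 20 tested macrophage markers 4 were at or above 5 CPM in IL5Tg and 0 belonged to another list; the abundant Apoe was at 12.31 ± 2.40 CPM in IL5Tg and 251 ± 97.3 in mdx. The sort excluded cells positive for MHC class II, CD11c or Gr1, which would remove part of the macrophages, and expression of these genes by eosinophils of dystrophic muscle stays open, since bulk libraries do not separate the cells.

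Mitochondrially encoded transcripts were low in mdx S5, by a median of -3.51 (SE 0.89 over 13 genes) against mdx S4 and S6. The same library held 9.09% of its counts in 7S RNA genes, against 3.33% and 2.98% in mdx S4 and S6 and 9.07% in IL5Tg S7, where mitochondrially encoded transcripts held 2.29%. Its 10 most abundant genes held 16.5%, against 11.95% and 12.01%, and it had a trend with GC content (Spearman's rho = 0.395 across nuclear genes, which are not independent replicates), but GC content bias as the whole cause is argued against, since 1778 nuclear genes of the same GC range moved by -0.56, 2.95 less (a difference of -2.95). Abundant RNAs taking up the counts would lower all other genes alike, but the 13 mitochondrially encoded genes fell further than nuclear ones. The medians of their log2 differences in share of counts lay -3.43 apart. The cause, differences in RNA quality or preparation included, stays open, and no biological explanation was tested, since the labels give none that sets this library apart.

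Il5 transcripts were abundant in cells sorted as eosinophils from transgenic animals, from 9775 to 33608 counts per library; the sort took cells positive for Siglec-F, which would remove most lymphocytes. The summed CPM of Cd3e, Cd3g and Trac was 0.699 times that of mdx libraries (means 0.239 and 0.342). They had at most 7, 2 and 15 counts in a transgenic library, where Il5 averaged 564 CPM. By these markers T cell RNA was scarce. Whether it was the source of Il5 cannot be told apart, since the Il5 level of a transgenic T cell was not measured. A few such cells are not excluded. Cd3d had 43 to 83 counts against 5 to 9 in mdx, 10.6 times the CPM, a difference the other 3 summed did not share, and since the labels do not name the transgenic line, whether these counts come from T cells or from the construct stays open. RNA of type 2 innate lymphoid cells stays open as well: Gata3, Areg, Il7r and Rora summed to 0.338 times the mdx level, but Gata3 and Areg had at most 12 and 13 counts, and other cells also express Il7r and Rora. Expression of the transgene in the sorted cells was not tested, since the file gives no reads within genes.

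The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1147, 3433 and 3298 genes in mdx_IL5Tg against IL5Tg, mdx against mdx_IL5Tg and mdx against IL5Tg. Others called at most 1, 0 and 0. These mix the groups, which widens spread and lowers calls, so chance stays open.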
